A study of Rattus norvegicus with 6 samples.

How the data were processed

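The data are 6 arrays of total RNA from beta cell-enriched preparations of male Wistar rats, 3 from postnatal day 20 and 3 from young adults of about 2 months. Per the labels, each array held 1 preparation, RNA was extracted with Trizol, and biotin-labelled target was made with a whole-transcript kit. The series' design text says that the cells were sorted by forward scatter, side scatter and autofluorescence and calls them primary cultured, without a culture time. Groups were taken from the sample titles, which also number the replicates.

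The deposited values are log2 signals per probe set, processed by the authors with RMA per the submitters' processing notes. RMA corrects the background, makes the arrays' distributions alike by quantile normalization and summarises the probes of a probe set. It assumes that most genes do not differ between arrays, and it compresses differences at both ends of the scale. That the values are on a log2 scale was taken from their range, 1.73 to 14.7, and their medians, 6.35 to 6.39. The software and its version, the annotation and the genome build are not given in the sources used here, so no coordinates are given. The table held 29214 probe sets and 0 columns of other series, and no detection calls.

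Probe sets were named through a table of the array's platform annotation, with symbols updated by Entrez identifier (15279 probe sets) or by accession (6) through a table of RefSeq rat genes, and the annotation's own symbol kept for 25. Of the probe sets 15310 had 1 gene symbol, 323 had several and 13581 were not listed there, and the last 2 kinds are unnamed here. The 15310 probe sets stood for 14506 genes. For 527 genes with several probe sets the one with the highest mean over all 6 arrays was used, a choice made without the groups. Among the named genes, probe sets of Cd36 differed most in size, with log2 differences of -2.70 and -1.56. No filter on low signal was applied.

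Adult was compared with day 20 on the log2 scale with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 14506 genes and a threshold of 0.05. Counts of at least 2-fold changes add a log2 difference of at least 1. Adjusted p-values of genes come from this model, and those of lists from camera of limma on the same design, two-sided, adjusted over 34 lists, with a preset correlation between genes of 0.01. Each list was also tested with a correlation estimated from its own residuals and with fry. Lists comprised 25 processes and 9 cell types. They held 1080 symbols, some of them older and newer names of 1 gene, of which 914 matched a measured gene, and the rest are not analysed here. The other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

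The tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except for those said to be chosen after. Named genes were the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, with a mean log2 signal of at least 7 in the higher group and no provisional symbol; the 2 largest rises and falls past the threshold in each list; 28 genes fixed in advance, of which 7 are not analysed here; and the 3 brightest members of each cell type list. The mean of 12 pan-endocrine genes (Chga, Chgb, Scg2, Scg3, Scg5, Pcsk2, Pcsk1n, Cpe, Resp18, Ptprn, Ptprn2 and Scgn) was defined after the data were seen.

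The fit was tested on simulated arrays with the means and spreads of the 14506 genes and 200 changed genes. It called 62.7% of genes changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 100% of those changed by 2, and 0.105% of unchanged genes. The 1 list raised by 0.3 was called by camera, and 0 of the 33 other lists were. The simulated genes varied independently, which real genes of a list do not.

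Alternatives were a second quantile normalization, centring on the median, removal of the lower 33.3% of genes by mean signal, eBayes with a trend and robust variances, the mean of a gene's probe sets, all probe sets, array weights, a test against a 1.2-fold change, the replicate number as a block, removal of cell type marker genes, camera on ranks, and each array left out in turn.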

Results

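Total RNA from beta cell-enriched preparations of the pancreas of male Wistar rats was hybridised to whole-transcript arrays at 2 ages. Cells had been sorted by light scatter and autofluorescence, properties by which beta cells are enriched without an antibody. The immature group held 3 preparations from animals at postnatal day 20, which the series describes as the start of a critical period of pancreatic maturation. The mature group held 3 preparations from young adults of about 2 months (250 to 280 g). The labels call the 3 preparations of each age biological replicates and do not say how many animals went into each. The design sets the immature against the mature cells, to find the expression changes that go with the functional maturation of rat beta cells. Values are log2 signals after RMA, the authors' normalization of the arrays, and a difference of 1 is a 2-fold change. The median log2 signal of an array lay between 6.35 and 6.39, and the first quartile between 4.91 and 4.94. The arrays came without detection calls, so a signal near the first quartile is not shown to be above background, and a fold over it is read as a lower bound. Precision is limited by the number of arrays, 3 per age, and means are given with the SD over these 3.

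The preparations differed by age more than within an age. Across 14506 genes, Pearson's r between arrays of the same age lay between 0.992 and 0.997, and between arrays of different ages between 0.972 and 0.983, with genes not being independent replicates. The first principal component, with 69.5% of the variance, placed the 3 adult arrays between -31.0 and -19.5 and the 3 day 20 arrays between 18.99 and 25.83. Both insulin genes were near the top of the scale at both ages, with log2 signals of 14.31 ± 0.04 in adult and 13.996 ± 0.20 at day 20 for Ins1, and 14.30 ± 0.02 and 14.10 ± 0.20 for Ins2 (SD, n = 3). Genes of digestive enzymes, the product of acinar cells, also had signals near the top of the scale. Of the 20 brightest genes over the 6 arrays, 17 were in the acinar list, with Ctrb1 (chymotrypsinogen) first at 14.604 ± 0.03 in adult and 14.57 ± 0.13 at day 20 (n = 3). Array signals this near the top of the scale respond less than in proportion to RNA.

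Adult beta cell-enriched preparations had higher signals of the incretin receptor Glp1r, the growth factor Tgfb3 and the protease inhibitor Mug1, than those of day 20 pups. Signals of the cell division genes Top2a and Rrm2, of the caveolar gene Cav1 and of Vim, here a fibroblast and stellate cell marker, were lower in adult. Of 14506 genes tested, 3294 changed with age at an adjusted p under 0.05, of which 1718 were higher and 1576 lower in adult. At least 2-fold changes were found for 221 higher and 195 lower genes. The groups did not overlap for 39.6% of genes, against 10% by chance for 3 arrays against 3.

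The largest measured rise was that of Mug1 (probe set 10858459), a murinoglobulin of the alpha-macroglobulin family of protease inhibitors, which was at least 30.5-fold higher in adult (9.78 ± 0.55 against 4.85 ± 0.32, SD, n = 3, adjusted p = 3.5e-05). Its day 20 mean lay below the first quartile of the arrays, so the size of the rise is not known. Its relative Mug2 was 7.28-fold higher, and the near-identical sequences of this family can share probes. Tgfb3 (probe set 10891303), a ligand of the transforming growth factor beta family, was 10.8-fold higher (9.90 ± 0.23 against 6.46 ± 0.14, n = 3, adjusted p = 1.3e-05). Rab30, a small GTPase of the Golgi, was 5.63-fold higher, and Cyfip2, a regulator of actin assembly, 5.20-fold. Glp1r (probe set 10829046), the receptor of the incretin GLP-1, was 4.65-fold higher (11.21 ± 0.35 against 8.996 ± 0.63, n = 3, adjusted p = 0.0012). The other genes among the 10 largest rises were Cyp7b1, an oxysterol hydroxylase (4.44-fold), Vsnl1, a neuronal calcium sensor (4.35-fold), Aass, an enzyme of lysine breakdown (4.33-fold), and Fam3b, a secreted protein of islets (4.31-fold).

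The largest measured fall was that of Cav1 (probe set 10853816), the caveolar coat protein, which was 9.21-fold higher at day 20 (8.71 ± 0.56 against 5.50 ± 0.14 in adult, SD, n = 3, adjusted p = 8.1e-05). Vim, the intermediate filament protein vimentin, was 7.01-fold higher at day 20 (9.78 ± 0.34 against 6.97 ± 0.26, n = 3, adjusted p = 5.3e-05). Genes of dividing cells made up 5 of the 10 largest falls, namely Ska3 and Bub1 of the kinetochore, the ribonucleotide reductase subunit Rrm2, the topoisomerase Top2a and the cyclin Ccna2, with day 20 levels 5.83- to 6.81-fold above adult. The others were Cd48, a surface protein of blood and endothelial cells (at least 7.21-fold higher at day 20), the fatty acid transporter Cd36 (at least 6.52-fold) and Apold1, a gene of endothelial cells (at least 5.75-fold). Their adult means of 4.77, 4.97 and 4.67 lay at or near the first quartile, and that of Bub1, at 5.17, was little above it. Of 138 genes named by fixed rules, 117 passed the threshold, and 94 of these passed it with each of the 6 arrays left out in turn. With the covariate described next, 54 of the 117 still passed. The rules on the largest rises and falls, over all genes and within each list, take only genes past the threshold. Most of the 117 were named by these rules, so that count is largely set by the choice. The 94 include genes picked for large changes.

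The mean of 12 pan-endocrine genes of the secretory pathway was higher in adult (10.84 ± 0.35 against 9.92 ± 0.51, SD, n = 3) and varied within each age, from 10.55 to 11.24 over the adult and from 9.39 to 10.40 over the day 20 arrays. All 12 are genes of prohormone processing and granules, which may also rise within beta cells. Their mean is thus not a measure of endocrine share alone. With this mean as a covariate, chosen after the data were seen, 773 genes passed, and without the arrays with its adult maximum and its day 20 minimum (adult replicate 1 and day 20 replicate 2) 1861 did. Leaving out day 20 replicate 2 alone gave 2159 genes, with 1083 higher in adult, and leaving out day 20 replicate 1 gave 1065 higher in adult.

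**Figure D1:**
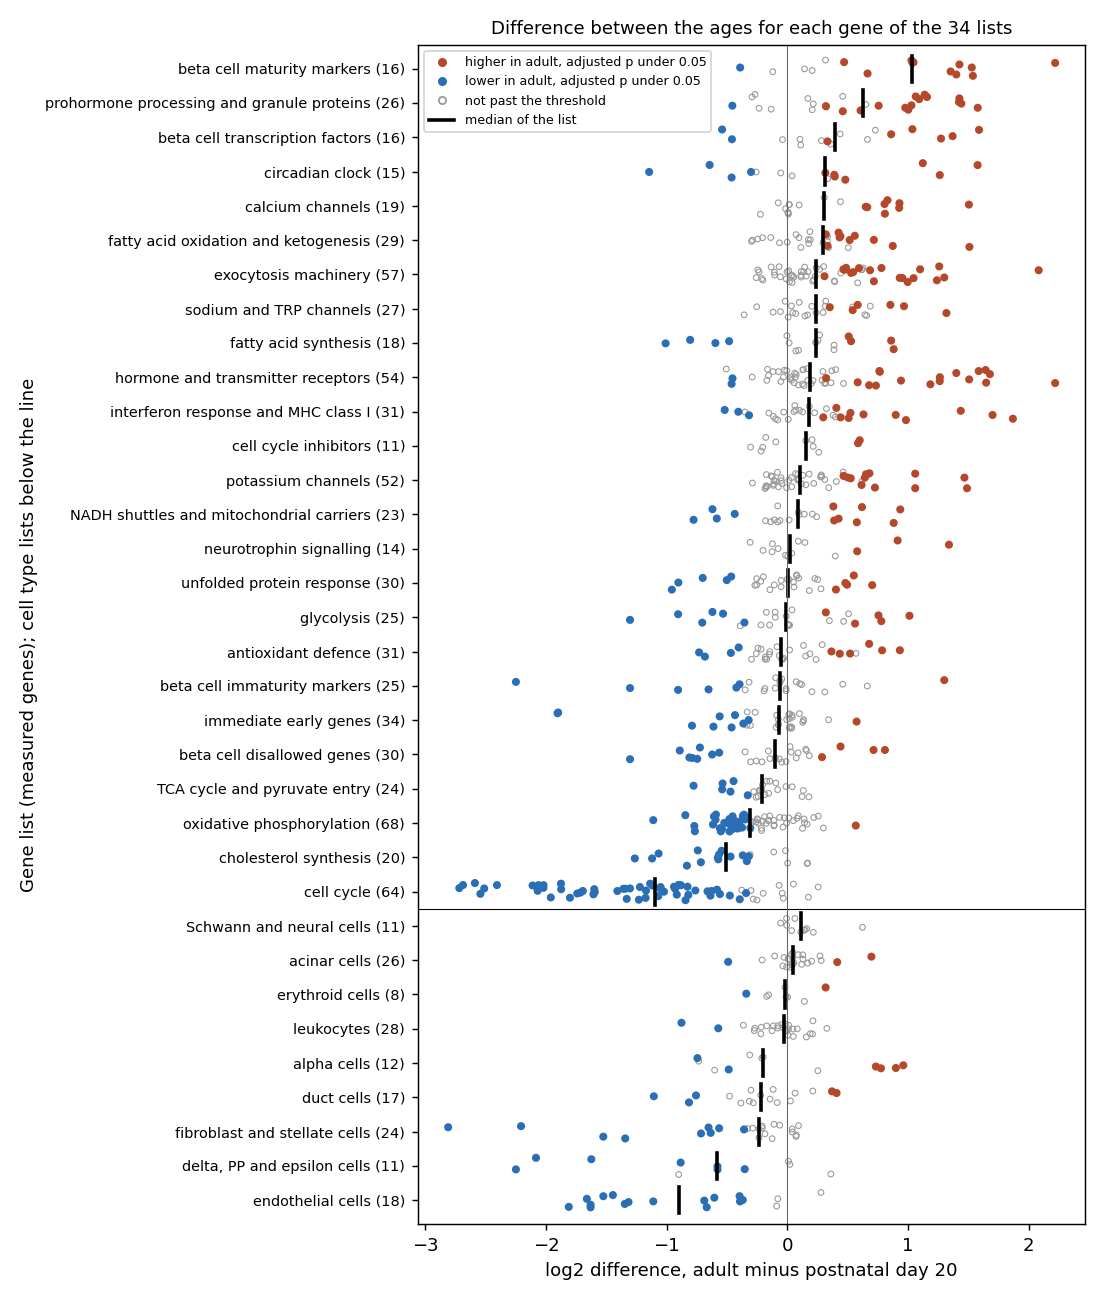
Each point is 1 measured gene of a list, placed by its log2 difference between the adult and the day 20 arrays (horizontal axis, 3 arrays per age), with filled points past an adjusted p of 0.05 and a bar at the median of the list. The cell cycle list lay farthest to the left, with a median of -1.09, and the beta cell maturity list farthest to the right, with a median of 1.03.

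Gene lists fixed before the data were examined were tested next, to ask which processes moved together with age. The lists of beta cell maturity markers, exocytosis genes, ion channels and receptors were called higher in adult, and those of the cell cycle, cholesterol synthesis, the citric acid cycle and oxidative phosphorylation lower. These calls were made with a preset correlation, and none held with an estimated one. Of 34 lists, 10 were called higher and 9 lower in adult by camera with its preset correlation of 0.01. With a correlation estimated for each list from its residuals, 0 of 34 were called after adjustment, 2 had an unadjusted p under 0.05 (cell cycle and cholesterol synthesis), and the smallest adjusted p was 0.334. That setting also takes its p-values from the residual degrees of freedom of only 6 arrays, so it has little power. The potassium channel list lost its call (camera adjusted p = 0.335) though its estimated correlation, 0.0073, was below the preset one. Loss of a call in that setting therefore does not show that correlation between genes had made the call. The test fry, which does not compare a list with other genes, called 24. It lost the list of prohormone processing and granule proteins (adjusted p = 0.0985). It added those of immaturity, cell cycle inhibitors, neurotrophins, the clock, duct cells and Schwann cells.

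Most measured markers of beta cell maturity rose with age. Of 16 measured members, 11 were higher and 1 lower in adult (12 and 1 adjusted over the list alone), with a median log2 difference of 1.03 (camera adjusted p = 1.9e-05, adjusted p = 0.337 with an estimated correlation). Besides Glp1r, Slc2a2, the glucose transporter GLUT2 of rodent beta cells, was 2.90-fold higher in adult (11.53 ± 0.39 against 9.998 ± 0.49, n = 3, adjusted p = 0.0036). Ucn3, the peptide urocortin 3, was 2.55-fold higher (adjusted p = 0.0036), the transcription factor Nkx6-1 2.05-fold (adjusted p = 0.0047) and Iapp, the amyloid peptide secreted with insulin, 2.04-fold (adjusted p = 0.0069). Adcy5, an adenylyl cyclase with a low signal, was the member that fell, by 0.39 on the log2 scale, a call lost without adult replicate 1 or 3 or day 20 replicate 1 or 2 (adjusted p up to 0.11). Ins1 and Ins2 did not pass (log2 differences of 0.32 and 0.21, adjusted p = 0.072 and 0.23). Ins1 passed with eBayes with trend and robust (adjusted p = 0.030), with array weights (0.029) and without day 20 replicate 1 (0.029). Over the same arrays the pan-endocrine mean was 0.92 higher in adult. With it as a covariate the list kept its camera call at the preset correlation (adjusted p = 1.3e-04), with a median difference of 0.43. An estimated correlation was not used with the covariate. The difference of the mean of all members then had a 95% interval of -0.0068 to 0.84. In the gene-wise fit with the covariate 1 member passed, Glp1r, with a log2 difference of 1.196 (adjusted p = 0.011).

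**Figure D2:**
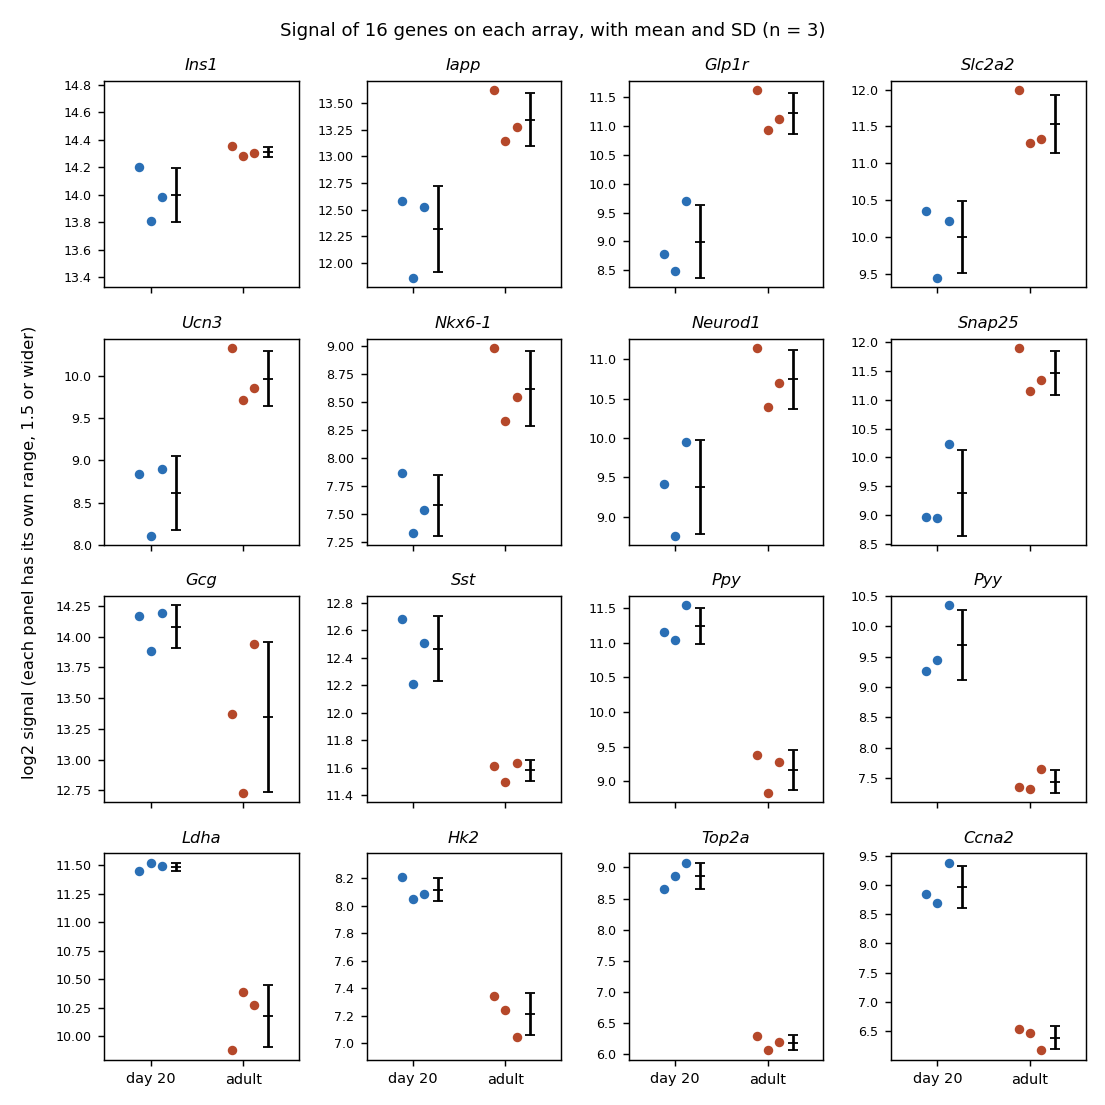
Log2 signal (vertical axes, a separate range of 1.5 or more per panel) of 16 genes on the 3 day 20 (blue) and 3 adult (red) arrays, with mean and SD beside the points. Glp1r lay at 8.996 ± 0.63 at day 20 and 11.21 ± 0.35 in adult, whereas Top2a lay at 8.87 ± 0.21 and 6.18 ± 0.12.

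Transcription factors of the beta cell list moved both ways, with more members rising. Of 16 measured, 6 were higher and 2 lower in adult (10 and 2 adjusted over the list alone; camera adjusted p = 0.0095, adjusted p = 0.337 with an estimated correlation). Rfx6, which acts in islet development, was 3.01-fold higher and Neurod1, an activator of insulin transcription, 2.58-fold. Gata4 and Nr5a2, both also expressed in the exocrine pancreas, fell by 0.54 and 0.46 on the log2 scale. With the pan-endocrine mean as a covariate the list had an adjusted p of 0.48.

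Markers of immature beta cells gave no call as a list (camera adjusted p = 0.084). Of 25 measured, 6 fell and 1 rose (6 and 1 adjusted over the list alone). The list was called lower without adult replicate 2 (adjusted p = 0.049), without day 20 replicate 2 (0.039) and by fry (0.032). Over all arrays its adjusted p was 0.454 with an estimated correlation. The hormone gene Pyy, which is also in the list of delta, PP and epsilon cells, was 4.75-fold higher at day 20. Ldha, which makes lactate, was 2.47-fold higher at day 20 (11.48 ± 0.04 against 10.18 ± 0.27, n = 3, adjusted p = 3.8e-04) and the hexokinase Hk2 1.87-fold. Syt4, a calcium-insensitive synaptotagmin that is also in the exocytosis list, rose, by 2.46-fold. Its place among the immaturity markers was set when the lists were fixed and is not shown by these data. Npy and Hk1 did not pass (log2 differences of 0.46 and -0.10, adjusted p = 0.067 and 0.73), though Npy passed with array weights (adjusted p = 0.028) and with the replicate number as a block (0.037). The list of genes that beta cells are held to keep silent, the disallowed genes, was called lower, with 8 of 30 lower and 4 higher in adult (9 and 4 adjusted over the list alone; camera adjusted p = 0.037, adjusted p = 0.449 with an estimated correlation). Besides Ldha, the chemokine gene Cxcl12 fell, by 0.89 on the log2 scale, while Arap2 and Ndrg2 rose by 0.81 and 0.71, that of Ndrg2 not holding when any 1 of the 3 day 20 arrays was left out (adjusted p up to 0.10). The call of the list was lost without adult replicate 1 (adjusted p = 0.14), without day 20 replicate 1 (0.066), with genes of low signal removed (0.080) and on ranks (0.078), and with the pan-endocrine mean as a covariate (0.42).

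The ion channel genes that passed the threshold were all higher in adult, but most measured members of the calcium, potassium and sodium lists did not pass. Of 19 calcium channel genes, 8 were higher in adult (8 adjusted over the list alone; camera adjusted p = 0.012, adjusted p = 0.337 with an estimated correlation), led by the auxiliary subunit Cacna2d1 (2.84-fold). The pore subunits of the L-type current, Cacna1c and Cacna1d, were 1.90-fold and 1.57-fold higher (adjusted p = 0.043 and 0.044). Of 52 potassium channel genes, 12 were higher (12 adjusted over the list alone; camera adjusted p = 0.018, adjusted p = 0.335 with an estimated correlation), led by Kcnip3 (2.81-fold), a channel-binding protein, and Kcnma1 (2.76-fold), the large-conductance calcium-activated channel. Kcnj11, the pore of the ATP-sensitive potassium channel, was 1.602-fold higher (adjusted p = 0.045), and its partner Abcc8, the sulfonylurea receptor, did not pass (log2 difference of 0.66, adjusted p = 0.097). With each of the 6 arrays left out in turn, Abcc8 passed in 1 fit, and its log2 difference ranged from 0.42 to 0.87. Of 27 sodium and TRP channel genes, 6 were higher (6 adjusted over the list alone; camera adjusted p = 0.0089, adjusted p = 0.337 with an estimated correlation), including Scn3b (2.49-fold). Trpa1 was counted too, at signals near or below the first quartile (5.13 in adult against 4.16), and is absent once genes of low signal are removed. Single-gene calls of Cacna1c, Cacna1d, Kcnj11, Kcnip3 and Scn3b were lost when day 20 replicate 1 or 2 was left out (adjusted p up to 0.14, 0.13, 0.15, 0.064 and 0.098). The call of Kcnj11 was also lost without each adult array, and that of Scn3b without adult replicate 1 or 3. The call of Cacna1c was also lost without adult replicate 1, and that of Cacna1d without adult replicate 2 or day 20 replicate 3. All 3 channel lists lost their call with the pan-endocrine mean as a covariate (adjusted p = 0.39, 0.24 and 0.36).

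Exocytosis genes were higher in adult as a list with the preset correlation, and 38 of 57 members did not pass on their own. Of the rest, 19 were higher and 0 lower in adult (21 and 0 adjusted over the list alone; camera adjusted p = 7.4e-05, adjusted p = 0.337 with an estimated correlation). Snap25, a plasma membrane SNARE protein, was 4.23-fold higher (11.47 ± 0.39 against 9.39 ± 0.74, n = 3, adjusted p = 0.0030). The list of prohormone processing and granule genes was also called higher by camera, but not by fry (adjusted p = 0.0985), with 15 of 26 up and 1 down (17 and 1 adjusted over the list alone; camera adjusted p = 1.2e-04, adjusted p = 0.454 with an estimated correlation), among them carboxypeptidase E, Cpe (2.98-fold), secretagogin, Scgn (2.72-fold), and the convertase Pcsk2 (2.23-fold). Calls of Scgn and Pcsk2 were lost without adult replicate 1 or day 20 replicate 1 (adjusted p up to 0.065 and 0.065), and that of Pcsk2 also without day 20 replicate 2. Dbi, an acyl-CoA binding protein, fell by 0.46 on the log2 scale. The 12 genes of the pan-endocrine mean belong to this granule list. With that mean as a covariate the exocytosis list had a camera adjusted p of 0.089. The granule list had one of 0.53 with the 12 genes still in it, which made its loss of call likely in advance. Over its 14 members outside the mean, the median log2 difference went from 0.32 to 0.12 with the covariate.

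The list of receptors for hormones and transmitters was called higher in adult, with 17 of 54 higher and 2 lower in adult (17 and 2 adjusted over the list alone; camera adjusted p = 6.6e-05, adjusted p = 0.335 with an estimated correlation). After Glp1r the largest rise was that of Gcgr, the glucagon receptor (3.20-fold, adjusted p = 0.0015). Vipr1 fell by 0.46 on the log2 scale. Htr3a, counted as the other lower gene, lay around the first quartile at both ages (4.62 in adult against 5.07) and is absent once genes of low signal are removed. Among the 14 genes of neurotrophin signalling, whose list was not called (camera adjusted p = 0.33), 3 were higher (3 higher and 1 lower adjusted over the list alone), with Ntrk2, the receptor of BDNF, up 2.53-fold and the sorting receptor Sort1 up 1.88-fold.

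Nearly all genes of the mitochondrial respiratory chain that passed the threshold fell. In the oxidative phosphorylation list 33 of 68 genes were lower and 1 was higher in adult (38 and 2 adjusted over the list alone), with a median log2 difference of -0.31 (camera adjusted p = 6.6e-09, adjusted p = 0.337 with an estimated correlation). Ndufa9 of complex I was 2.16-fold higher at day 20 (10.09 ± 0.10 against 8.98 ± 0.26, n = 3, adjusted p = 7.5e-04) and Cox6a1 of complex IV 1.80-fold, while Ndufa10 rose 1.48-fold. With the pan-endocrine mean as a covariate the list kept its camera call at the preset correlation (adjusted p = 1.8e-04), with a median of -0.20, and 2 members passed. An estimated correlation was not used with the covariate. The difference of the mean of all members then had a 95% interval of -0.46 to 0.08. In the citric acid cycle list 6 of 24 were lower and 0 higher (6 and 0 adjusted over the list alone; camera adjusted p = 8.2e-04, adjusted p = 0.335 with an estimated correlation), led by the dehydrogenases Mdh2 and Idh2, which fell by 0.78 and 0.54 on the log2 scale. Glycolysis genes moved both ways, with 5 of 25 higher and 6 lower (7 and 6 adjusted over the list alone; camera adjusted p = 0.47). Eno2 and Pkm were 2.02-fold and 1.72-fold higher in adult and Ldha and Hk2 lower. Genes of NADH shuttles and mitochondrial carriers were likewise mixed, with 7 of 23 higher and 4 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.58). The malic enzymes Me2 and Me1 rose by 1.91-fold and 1.84-fold, and the glutamate carrier Slc25a22 fell by 0.62 on the log2 scale. Both malic enzyme calls were lost without day 20 replicate 1 or 2 (adjusted p up to 0.056 and 0.15), and that of Me1 also without adult replicate 1 or 3.

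Most cholesterol synthesis genes fell, with 14 of 20 lower and 0 higher in adult (15 and 0 adjusted over the list alone), a median log2 difference of -0.51 (camera adjusted p = 8.6e-07, adjusted p = 0.335 with an estimated correlation) and day 20 levels 2.40-fold higher for Fdps and 2.17-fold for Idi1, enzymes of the mevalonate pathway. The fatty acid oxidation list was called higher, with 10 of 29 higher and 0 lower (13 and 0 adjusted over the list alone; camera adjusted p = 6.2e-04, adjusted p = 0.337 with an estimated correlation). Ehhadh of the peroxisome was 2.84-fold higher and Hadh of the mitochondrion 1.83-fold. Fatty acid synthesis genes went both ways, with 4 of 18 higher and 4 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.51). Fasn, the fatty acid synthase, was 2.01-fold higher at day 20 and Dgat2 1.75-fold, whereas Mlxipl, the glucose-responsive factor ChREBP, was 1.81-fold higher in adult, a call lost without day 20 replicate 2 (adjusted p = 0.063).

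Cell cycle genes had the lowest median difference of the 34 lists. Of 64 measured, 53 were lower and 0 higher in adult (56 and 0 adjusted over the list alone), with a median log2 difference of -1.09 (camera adjusted p = 4.6e-34, adjusted p = 0.334 with an estimated correlation). Rrm2 was 6.58-fold higher at day 20 (9.11 ± 0.34 against 6.39 ± 0.11, n = 3, adjusted p = 3.5e-05) and Top2a 6.44-fold (8.87 ± 0.21 against 6.18 ± 0.12, n = 3, adjusted p = 2.6e-05). With the pan-endocrine mean as a covariate 44 members passed. The mean of the endothelial markers was also higher at day 20, at 6.80 ± 0.24 against 5.88 ± 0.03 in adult (SD, n = 3). Of 11 cell cycle inhibitors, the retinoblastoma family genes Rbl2 and Rb1 were 1.52-fold and 1.501-fold higher in adult and 0 were lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.51), and Cdkn2a, which encodes p16, had a low signal and a log2 difference of -0.22 that did not pass (adjusted p = 0.24). The call of Rb1 was lost without adult replicate 3 or day 20 replicate 1 (adjusted p up to 0.06).

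The immediate early list was called lower, with 9 of 34 lower and 1 higher in adult (10 and 1 adjusted over the list alone; camera adjusted p = 0.013, adjusted p = 0.454 with an estimated correlation), led by Egr2 (3.74-fold higher at day 20) and Klf2 (3.73-fold), the second a gene also induced in endothelial cells. This call was lost without day 20 replicate 1 (adjusted p = 0.076) and with the pan-endocrine covariate (0.093). The list of the interferon response and MHC class I was called higher, with 11 of 31 higher and 3 lower (14 and 3 adjusted over the list alone; camera adjusted p = 0.0062, adjusted p = 0.337 with an estimated correlation), led by Usp18 (3.65-fold) and Ifi27 (3.25-fold), while the immunoproteasome subunit Psmb10 fell by 0.52 on the log2 scale. Clock genes divided, with 7 of 15 higher and 4 lower (8 and 5 adjusted over the list alone; camera adjusted p = 0.30). Bhlhe41 was 2.98-fold and Nr1d1 2.40-fold higher in adult, and Per2 was 2.21-fold and Per3 1.56-fold higher at day 20. The time of day of sampling is not given in the sources used here. The unfolded protein response list had 5 of 30 higher and 5 lower (6 and 8 adjusted over the list alone; camera adjusted p = 0.63), with Creld2 and Sdf2l1 lower by 0.96 and 0.90 on the log2 scale and Dnajb9 1.63-fold higher. The antioxidant list had 6 of 31 higher and 4 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.84), with Gclm, a subunit of the enzyme that limits glutathione synthesis, 1.91-fold higher.

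Of the 9 lists of other cell types, 3 were called lower in adult and 0 higher. Endothelial markers were lower in adult, with 15 of 18 lower and 0 higher (15 and 0 adjusted over the list alone; camera adjusted p = 9.9e-10, adjusted p = 0.337 with an estimated correlation), and their mean was 5.88 ± 0.03 in adult against 6.80 ± 0.24 at day 20 (SD, n = 3). Emcn was 3.51-fold and Pecam1 3.10-fold higher at day 20. The list of fibroblast and stellate cell markers was called lower, with 9 of 24 lower, 0 higher and 15 not past the threshold (11 and 0 adjusted over the list alone; camera adjusted p = 2.4e-05, adjusted p = 0.337 with an estimated correlation), led by Vim and the matrix protein gene Sparc (4.61-fold). Markers of delta, PP and epsilon cells were lower, with 7 of 11 lower and 0 higher (7 and 0 adjusted over the list alone; camera adjusted p = 3.4e-04, adjusted p = 0.335 with an estimated correlation). Ppy, pancreatic polypeptide, was 4.23-fold higher at day 20 (11.24 ± 0.26 against 9.16 ± 0.29, n = 3, adjusted p = 1.4e-04) and Sst, somatostatin, 1.85-fold (12.47 ± 0.24 against 11.58 ± 0.08, n = 3, adjusted p = 0.0016).

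Alpha cell markers went both ways, with 4 of 12 higher and 2 lower in adult (4 and 3 adjusted over the list alone; camera adjusted p = 0.84). Gcg, the glucagon gene, was bright at both ages and did not pass in the main fit (13.35 ± 0.61 in adult against 14.08 ± 0.17 at day 20, n = 3, adjusted p = 0.072). It passed in some alternatives, such as with the replicate number as a block (adjusted p = 0.028). Loxl4 and Tm4sf4 were 1.95-fold and 1.86-fold higher in adult, and Ttr fell by 0.74 on the log2 scale, a call lost without adult replicate 1 or 2 (adjusted p up to 0.071). The mean of 26 acinar genes was 13.78 ± 0.05 in adult and 13.70 ± 0.11 at day 20 (SD, n = 3), with 2 members higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.24), a list that was called higher without day 20 replicate 1 (adjusted p = 0.0071) and with the pan-endocrine covariate (0.044). Both of these calls used the preset correlation. That estimated for the acinar list over all arrays was 0.776, with an adjusted p of 0.790. Duct markers had 2 of 17 higher and 3 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.063), with Cftr 2.15-fold higher at day 20, and were called lower without adult replicate 1 (adjusted p = 0.046), adult replicate 2 (0.0499), day 20 replicate 2 (0.044) or day 20 replicate 3 (0.015), and by fry (0.032). They were also called lower with the replicate number as a block (camera adjusted p = 0.038) and without both adult replicate 1 and day 20 replicate 2 (0.029). Over all arrays the duct list had an adjusted p of 0.337 with an estimated correlation. The 2 higher were Anxa4 and Epcam, and both calls were lost without adult replicate 1 or 2 or day 20 replicate 1 or 2 (adjusted p up to 0.091 and 0.11). Leukocyte markers had 0 of 28 higher and 2 lower (0 and 2 adjusted over the list alone; camera adjusted p = 0.33). Cd68 and Rac2 fell by 0.88 and 0.57 on the log2 scale. Of 8 erythroid genes 1 was higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.71). The higher was Hbb, lost without any 1 array but adult replicate 2 (adjusted p up to 0.17), and the lower was Klf1, lost without any 1 of the 6 (adjusted p up to 0.14). Of 11 Schwann and neural genes 0 passed (0 adjusted over the list alone; camera adjusted p = 0.33). The median, the mean and the test differed in sign for 4 lists, namely the unfolded protein response, fatty acid synthesis, antioxidant and alpha cell lists, none of which was called.

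**Figure D3:**
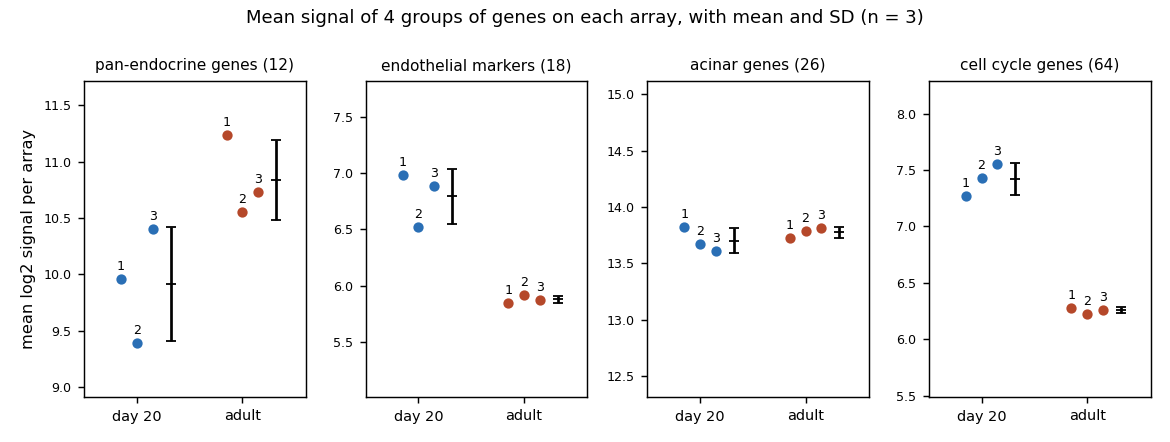
Mean log2 signal (vertical axes, equal spans) of the 12 pan-endocrine genes, 18 endothelial markers, 26 acinar genes and 64 cell cycle genes on each array, numbered by replicate, with mean and SD of the 3 arrays of an age. The endocrine mean was 10.84 ± 0.35 in adult and 9.92 ± 0.51 at day 20, and the endothelial mean 5.88 ± 0.03 and 6.80 ± 0.24.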

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

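The settings with the pan-endocrine mean as a covariate, and without both adult replicate 1 and day 20 replicate 2, were chosen after seeing the data. The count of 3294 changed genes lay between 2609 and 3806 under alternatives that kept all arrays and 1 value per gene. This range leaves out the covariate and a test against a 1.2-fold change. The latter gave 933 (446 higher, 487 lower), since it asks for a larger difference. The fit of all probe sets called 3903 probe sets, which are not genes, with more features tested. Of these, 1260 are unnamed here, 2502 stood for genes among the 3294, and 354 were at least 2-fold lower. With the pan-endocrine covariate 773 passed (307 higher, 466 lower, 83 at least 2-fold higher), 717 of them among the 3294, and without both arrays 1861 (937 higher, 924 lower, 126 at least 2-fold higher), 1765 of them among the 3294. Leaving out each array in turn, with fewer samples, gave 2159 to 2925 genes, 1065 to 1591 higher and 1076 to 1334 lower, with 152 to 294 at least 2-fold higher and 199 to 214 lower. The 19 called lists became 0 (0 higher, 0 lower) with an estimated correlation and 12 (5 higher) with the covariate, and numbered 18 to 21 with 1 array left out (10 to 11 higher, 7 to 11 lower). Higher with the covariate were the maturity, fatty acid oxidation, receptor, interferon and acinar lists, the last not among the 19. Lower were the citric acid cycle, oxidative phosphorylation, cell cycle, cholesterol, endothelial, fibroblast, and delta, PP and epsilon lists. These calls used the preset correlation. The cause of the changes under the covariate was not tested.

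Whether equal replicate numbers pair the samples is not given in the sources used here. The correlations of same-numbered deviations from the age means were -0.19, 0.19 and -0.21. Adult replicates 1 and 3 correlated best with another number. Deviations from a mean of 3 arrays constrain each other, so these values cannot exclude pairing. With the replicate block 2609 genes and 20 lists were called.

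Changes of sign were followed for the 138 named genes only, not for all genes tested. Of the named genes that changed sign only Kcnj11 had been called, and only Gc passed the threshold after the change. After a second quantile normalization Cel was at -0.010, Foxd3 at 0.0051 and Tal1 at 0.00079. Foxd3 was at 0.013 after centring, and with array weights Ets1 was at -0.0016 and Foxd3 at 0.017. With the covariate Abcc8 was at -0.25, Cd24 at 0.025, Elavl4 at -0.30, Ets1 at -0.23, Foxd3 at 0.16, Gc at -1.01 (adjusted p = 0.036), Hk1 at 0.34, Kcnj11 at -0.029, Tal1 at 0.11 and Tff2 at 0.049. Without both arrays Cel was at -0.0016, Ets1 at -0.11, Foxd3 at 0.094, Gc at -0.29, Hk1 at 0.13 and Tal1 at 0.070. With 1 array left out the ranges were -0.0011 to 0.10 for Cd79b, -0.037 to 0.078 for Cel, -0.017 to 0.10 for Cpb1, -0.014 to 0.11 for Ctrb1, -0.089 to 0.60 for Ets1, -0.046 to 0.060 for Foxd3, -0.11 to 0.71 for Gc, -0.23 to 0.087 for Hk1 and -0.065 to 0.033 for Tal1. Lists that turned had adjusted p-values far from the threshold. The antioxidant list was at 0.987 without low signals, 0.997 with the block and 0.860 on ranks, and the alpha cell list at 0.786 with the block, 0.769 on ranks, 0.463 with the covariate and 0.889 without both arrays. Fatty acid synthesis was at 0.987 by fry and 0.413 with the covariate, NADH shuttles at 0.731 with the covariate, and erythroid genes at 0.577 with it and 0.900 without both arrays. With 1 array left out the antioxidant list ranged from 0.694 to 0.992 and the alpha cell list from 0.594 to 0.935. Signals near the ends of the scale limit what is seen for the hormone and enzyme genes and for genes near background.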

Other observations

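The gene groups that follow were picked by symbol after the data were seen. Histone genes were lower in adult, with 22 of 29 lower and 0 higher and a median log2 difference of -0.75 (camera p = 1.3e-16, p = 0.0018 with an estimated correlation, both unadjusted). Of 37 genes of proteasome subunits, 19 were lower and 1 higher, with a median of -0.32 (camera p = 5.7e-08, p = 0.084 with an estimated correlation). Of 65 genes of mitochondrial ribosomal proteins, 27 were lower and 2 higher, with a median of -0.25 (camera p = 1.4e-07, p = 0.17 with an estimated correlation). Of the cytosolic ribosome, 11 of 69 genes were lower, 3 were higher and the median was -0.15 (camera p = 8.6e-04, p = 0.54 with an estimated correlation).

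Of 54 genes of Rab GTPases, which direct vesicle traffic, 15 were higher in adult and 2 lower, with a median of 0.20 (camera p = 9.0e-04, p = 0.046 with an estimated correlation, both unadjusted), Rab30 having the largest rise. Heat shock protein genes (6 of 35 higher, 6 lower), glutamate and GABA receptor genes (4 of 43 higher, 1 lower) and cytochrome P450 and sulfotransferase genes (4 of 80 higher, 6 lower) gave camera p-values of 0.90, 0.33 and 0.41. These are 8 groups in all, picked for interest. Of 13904 probe sets unnamed here, 1260 passed the threshold in a fit of all probe sets, 532 higher and 728 lower in adult.

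The tests in the rest of this part were chosen after the results were seen. For 3294 genes, the highest count among the other splits of the 6 arrays was 0, and for 19 lists it was 14, so that 1 of 10 splits, the real one, gave as large a count in each case. With 10 splits no share under 0.05 can be reached. Each of the other splits sets 2 arrays of an age with 1 of the other, so that part of the age difference stays in it.

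The rise of beta cell maturity markers may reflect a lower endocrine share of the RNA at day 20, since 9 of the 12 pan-endocrine genes rose too and their mean varied within each age. Against a loss of all endocrine types alike, Ppy and Sst were 4.23-fold and 1.85-fold higher at day 20, and the median of the delta, PP and epsilon list was -0.58 (-0.55 with the pan-endocrine mean as a covariate), which leaves a lower share of beta cells open. With that covariate, the difference of the mean of all 16 maturity genes went from 0.87 to 0.42, with a 95% interval from -0.0068 to 0.84 over 6 arrays. The same test, run first on the 11 members that had risen, gave 0.58 (0.10 to 1.06), but these were picked for the rise, so that all members were used instead. A lower share of endocrine or beta cells and a rise with age within beta cells, itself untested, cannot be told apart here. The interval of the full list reaches 0, and the insulin and acinar genes that would show the share are near the top of the scale. The 12 pan-endocrine genes are also granule genes that may themselves rise within beta cells, so that the covariate may remove such a rise. An interval clear of 0 would thus not have separated these explanations either.

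The fall of cell cycle genes went with more endothelial signal at day 20, and dividing endothelial cells might have brought it. With the endothelial mean as a covariate the difference of the mean of 64 cell cycle genes was -1.32 (95% interval -2.30 to -0.34), against -1.16 without it, and with the pan-endocrine mean it was -1.25 (-1.70 to -0.79). The endothelial mean hardly varied among the adult arrays (5.85 to 5.92), so its slope rests mainly on the 3 day 20 arrays. That test therefore cannot tell whether dividing endothelial cells brought the fall. As far as the pan-endocrine mean follows the endocrine share, its test argues against a lower share as the whole cause. Few arrays stand behind the slope. Division of the beta cells themselves, or of other cells such as acinar cells or fibroblasts, stays open and was not tested.

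The fall of oxidative phosphorylation genes could come from a shift of bright genes left by the normalization or from the endocrine share. The median of -0.31 lay below all 10000 random lists matched on mean signal, whose lowest was -0.15 and whose 95% range was -0.05 to 0.15, which argues against the first. With the pan-endocrine covariate the difference of the mean of 68 genes went from -0.28 to -0.19 (95% interval -0.46 to 0.08), so that the endocrine share and age cannot be told apart for this list, its interval holding both 0 and the unadjusted value. The 33 members that had fallen, tested first and picked for the fall, gave -0.39 (-0.71 to -0.07).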
